A study of Arabidopsis thaliana with 12 samples.

How the data were processed

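Arabidopsis thaliana seedlings 12 days old were compared in 4 groups of 3 libraries, for 12 libraries in all. The groups were the wild type Col-0 and RNAi-MARS, a line with an RNA interference construct against the long non-coding RNA MARS, each collected before (0 h) and 4 h after spraying with 10 µM of the plant hormone abscisic acid (ABA), per the labels. Polyadenylated RNA of whole seedlings was sequenced. The design has no unsprayed group at 4 h, so a change between 0 h and 4 h holds the hormone and the spraying together, and the time of day as well if the groups were harvested at different hours, which the labels do not say. Nothing in the labels says that the 3 libraries of a group came from separately grown cultures, so the p-values measure the spread between these samples, which may be technical in part.

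For each library the authors deposited an estimated count of reads per feature, without normalization. The submitters' processing notes name Trimmomatic 0.36, STAR 2.7.2a, featureCounts of Subread 1.6.5 and the genome build TAIR10. The trimming and alignment settings, the strand setting and the treatment of reads that match several places were not given in the sources used here. Between 5.31% and 7.60% of the features in a library held deposited counts that were not whole numbers, so reads had been divided between features. Counts of near-identical copies therefore hold parts of the same reads and move together, and counts of overlapping or antisense genes cannot be told apart where strand was not used; both kinds are given as uncertain. Reads from the RNA interference construct itself would also be counted to MARS. Each library had 69383 features, of which 37898 were nuclear genes, 31189 transposable elements, 134 plastid genes and 162 mitochondrial genes. All 37898 nuclear gene identifiers matched the reference table of TAIR10.1, which supplied gene names and coordinates, since the deposited tables hold identifiers and no coordinates.

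Total counts per library were between 19020202 and 38787804. The counts were rounded to whole numbers and tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on all 12 libraries, with 1 coefficient per group, TMM normalization, the filterByExpr filter at a minimum count of 10, and robust dispersion estimates. The filter kept 22465 features, of which 21784 were nuclear genes and 574 transposable elements. The 5 comparisons were the genotype effect before and after ABA, the ABA response in Col-0 and in RNAi-MARS, and the difference between those responses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, all adjusted p-values are from edgeR unless another tool is named, all tests are 2-sided, and the standard error (SE) is the log2 fold change divided by the square root of F. Levels are CPM, counts scaled to the same total in every library with TMM factors, as mean ± SD of 3 libraries.

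On simulated counts with known changes, the test recovered 93.9% of 4-fold, 53.0% of 2-fold and 18.5% of 1.5-fold changes for the genotype effect before ABA (22235 genes, 5 false calls). For the genotype effect after ABA it recovered 84.8%, 53.0% and 31.3% (22263 genes), for the ABA response 81.8%, 58.2% and 26.9% in Col-0 (22249 genes) and 87.7%, 66.7% and 22.7% in RNAi-MARS (22244 genes). For the interaction it recovered 84.8% of 4-fold, 25.8% of 2-fold and 3.08% of 1.5-fold changes (22235 genes, 9 false calls). Each simulation changed only 65 to 67 tested genes at each fold, in 1 group, and drew genes independently. In the data 8979 features were called for the ABA response in Col-0 and 9567 in RNAi-MARS. With so many changes the adjusted cutoff is less strict, so the simulated shares do not measure the sensitivity of those 2 comparisons.

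A total of 27 gene lists with 334 genes were fixed: the marneral cluster, other triterpene clusters, ABA clade A phosphatases, ABA receptors, ABA kinases and transcription factors, ABA response markers, ABA metabolism, circadian clock, touch and early wounding, jasmonate, salicylic acid, auxin response, photosynthesis, aliphatic glucosinolates, anthocyanin and flavonoids, root markers, root hair, stomatal lineage, flowers and flowering, cell cycle, polycomb and H3K27 demethylases, RNA silencing, heat shock, iron deficiency, phosphate starvation, sugar starvation and seed storage. Of these, 26 had at least 3 tested members; the 10 seed storage genes had too few to be tested. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of each comparison. Counts of called members are given over all tested genes and adjusted over the list alone.

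Genes were named by a fixed rule. For each comparison it takes every member of the marneral cluster and called genes within 100 kb of MARS. It further takes up to 10 called genes with the largest positive and 10 with the largest negative log2 fold change, among genes that have a name, a mean log2 CPM of at least 1 and groups that do not overlap, and the first 3 in each direction with or without a name. In place of non-overlapping groups, the interaction asked for a difference whose sign held on leaving out any library. Of each list it takes up to 4 called members with the smallest adjusted p or, where none was called, the 2 with the highest mean CPM. Members of lower rank were left out for length, and genes outside the rule are said to have been chosen after their values were seen.

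Values of the marneral cluster were also tested by exact permutation of the genotype labels within each time on log2 CPM. A root score per library was the mean, over 23 genes of the root marker and root hair lists, of the log2 CPM minus the gene's mean over all libraries; its correlations with single genes were taken on deviations from the group means. Similar genes inside a chromosome 1 segment were found with blastn 2.17.0, and tables were joined with Python 3.11.15. The groups, tests, gene lists, naming rule and a first set of alternatives were fixed before the data were examined. Those alternatives were the size factors of DESeq2 in edgeR, DESeq2 1.42.0, limma-voom, no filter, a stricter filter at 1 CPM and a mean count of 50, the replicate block, fits of the compared groups alone, dispersion estimates that were not robust, no organelle genes, a test against a 1.2-fold change (glmTreat), and leaving out each library. Added after seeing the data were summing the chromosome 1 segment, the root score as a covariate, leaving out 2 libraries with low root scores, leaving out transposable elements, the exact permutation for MARS, and the block in the similarity of effects.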

Results

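The transcriptome of whole Arabidopsis seedlings was measured in the wild type Col-0 and in RNAi-MARS, a line in which the long non-coding RNA MARS is targeted by RNA interference, before and 4 h after a spray with 10 µM ABA. The series asks how lowering MARS affects the response to this hormone. Each of the 4 groups had 3 libraries, named A, B and C. Total counts were 20394404, 28656043 and 34721018 in Col-0 before ABA and 29434969, 19020202 and 22458846 after it. In RNAi-MARS they were 25484448, 19942905 and 36933131 before ABA and 28146287, 38787804 and 20717031 after it. Log2 CPM of libraries of the same group correlated at 0.969 to 0.991 across genes, and every pair differed by more than sampling noise, with a chi-square per degree of freedom of at least 6.55. The first principal component held 60.7% of the variance and separated all libraries at 0 h (-70.4 to -51.0) from all libraries at 4 h (47.8 to 72.4). The second held 9.97% and separated neither the genotypes nor the times. Library C of RNAi-MARS before ABA had 0.104% of its counts on plastid genes, against at most 0.0256% in the others.

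MARS, the target of the construct, was lower in every RNAi-MARS library than in any Col-0 library of the same time. In Col-0 it stood at 6.63, 2.60 and 0.344 CPM before ABA and at 21.3, 9.09 and 20.1 CPM after it, for libraries A, B and C. In RNAi-MARS the values were 0.196, 0.156 and 0.167 CPM before and 2.303, 1.34 and 4.11 CPM after. The RNAi-MARS libraries before ABA held only 5, 3 and 6 counts of it. MARS (AT5G00580) is a 1941 bp gene on the plus strand of chromosome 5, at 17045300 to 17047240 of TAIR10.1, with 4 annotated transcripts, of which 3 have 2 exons. The log2 difference between genotypes was -4.12 ± 1.05 (SE, n = 3) before ABA and -2.74 ± 0.77 after it, and neither was called over all genes (edgeR adjusted p = 0.996 and 0.477). DESeq2 called the difference before ABA (-4.21, adjusted p = 0.00901) and gave no adjusted p for MARS after it. The difference before ABA was -3.04 without library A of Col-0 before ABA and -3.03 with limma-voom, not called in either. With the genotype labels permuted within both times, an added test of this gene alone gave a mean log2 difference of -2.85 and an exact p = 0.005, the smallest that 400 assignments can give (adjusted 0.015 over 6 values). Within a single time 3 against 3 libraries cannot go below an exact p = 0.1, the value found at both.

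The other genes of the marneral cluster, which makes a root triterpene, did not differ detectably between genotypes. Marneral synthase, MRN1 (AT5G42600), had 7.77 ± 7.56 CPM in Col-0 and 16.1 ± 16.0 in RNAi-MARS before ABA, and 18.6 ± 14.7 and 44.2 ± 16.0 after it (SD, n = 3). The log2 difference was 1.097 ± 1.05 before and 1.24 ± 1.00 after (adjusted p = 0.996 and 0.732; exact permutation p = 0.125 over both times). The cytochrome P450 genes CYP71A16 (-0.12 before, 0.77 after) and CYP705A12 (-0.63 and 0.11) gave exact permutation p = 0.605 and 0.88. Of the 4 tested cluster members edgeR called none in either genotype comparison, and adjusted over the list alone 1 was lower at each time, MARS itself. By edgeR none of 34 tested genes within 100 kb of MARS was called between genotypes, whether adjusted over all genes or over the list alone. The root score of the libraries did not separate the genotypes either (exact permutation p = 0.535), while among the libraries of Col-0 before ABA alone it varied from -0.776 to 0.568.

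**Figure D1:**
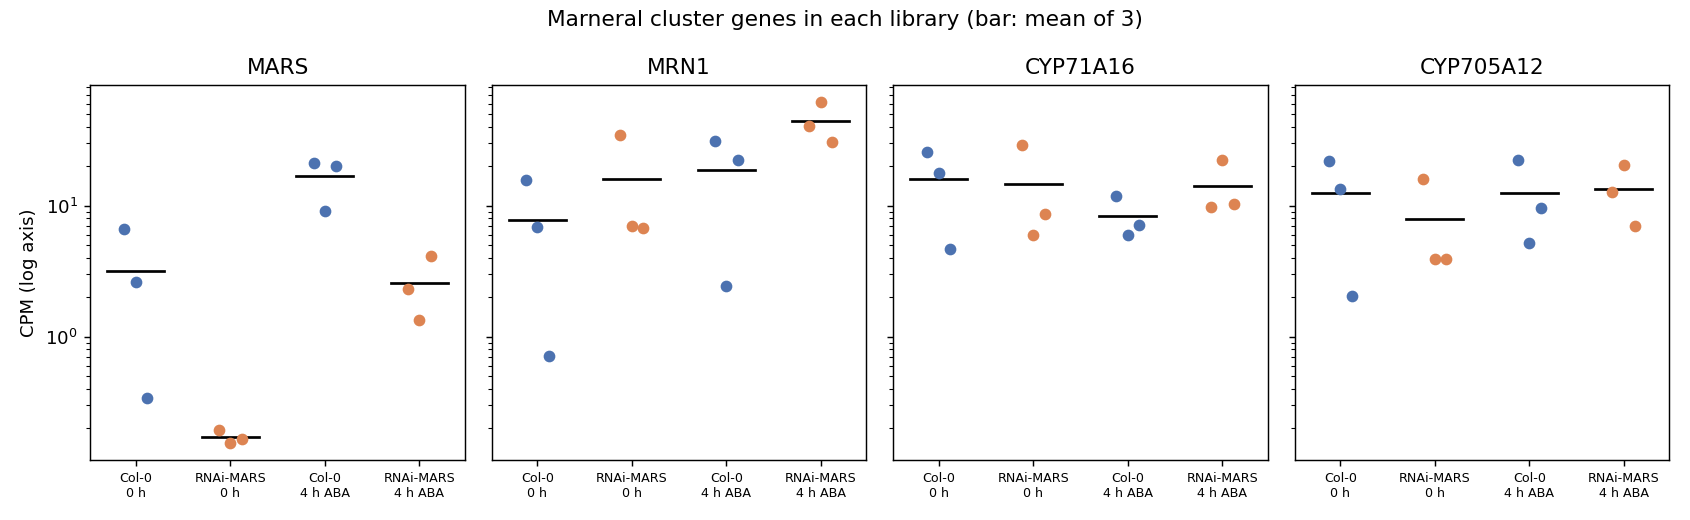
CPM on a log axis for MARS, MRN1, CYP71A16 and CYP705A12 in each of the 12 libraries, with each point a library and each bar the mean of the 3 libraries of a group. MARS lies between 0.156 and 0.196 CPM in RNAi-MARS before ABA and between 9.09 and 21.3 CPM in Col-0 after it, while the other genes overlap between genotypes.

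Between genotypes, 20 of 22465 features were called before ABA, 2 higher and 18 lower in RNAi-MARS, and the same 20 genes were called after ABA in the same directions. Of the 18 lower genes, 17 lie in 71.4 kb of chromosome 1, at 8765614 to 8837007 of TAIR10.1, where 6 of the 23 tested genes were not called, 4 of them similar to ASB1 with a median of -0.04 before ABA. They include LpxC1 to LpxC5, homologs of bacterial enzymes of lipid A synthesis, and the non-coding genes AT1G25098 and AT1G25175. LpxC2 (AT1G24880) fell from 166 ± 11.3 CPM in Col-0 to 42.5 ± 1.74 in RNAi-MARS before ABA, a log2 difference of -1.97 ± 0.11 (adjusted p = 3.12e-06), and was -1.48 ± 0.11 after it (adjusted p = 2.71e-05). AT1G25175 went from 184 ± 10.2 to 45.6 ± 1.45 CPM (-2.01 ± 0.10). The median log2 difference of the 17 genes was -1.97 before and -1.67 after ABA, and none of 36 tested genes in the 100 kb on either side was called (medians 0.02 and 0.04).

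The individual values of these 17 genes are uncertain, because the segment holds near-identical copies that divided reads between them. Several also overlap other genes, among them LpxC1, LpxC2, AT1G25098, AT1G25175, AT1G24800, AT1G25150 and AT1G25211. The counts of the whole segment summed do not depend on the division between copies inside it. Reads shared with similar genes outside still enter the sum, of which the 4 genes similar to ASB1 held at most 14.0 CPM in any library. The summed counts were 689 ± 29.4 CPM in Col-0 and 190 ± 4.06 in RNAi-MARS before ABA, a 3.63-fold difference, and 645 ± 26.6 and 238 ± 23.1 after it, a 2.71-fold difference (n = 3 each; adjusted p = 1.23e-05 and 9.15e-05). The smaller gap after ABA was 0.42 ± 0.14 on the log2 scale, which did not pass over all genes (adjusted p = 0.948).

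**Figure D2:**
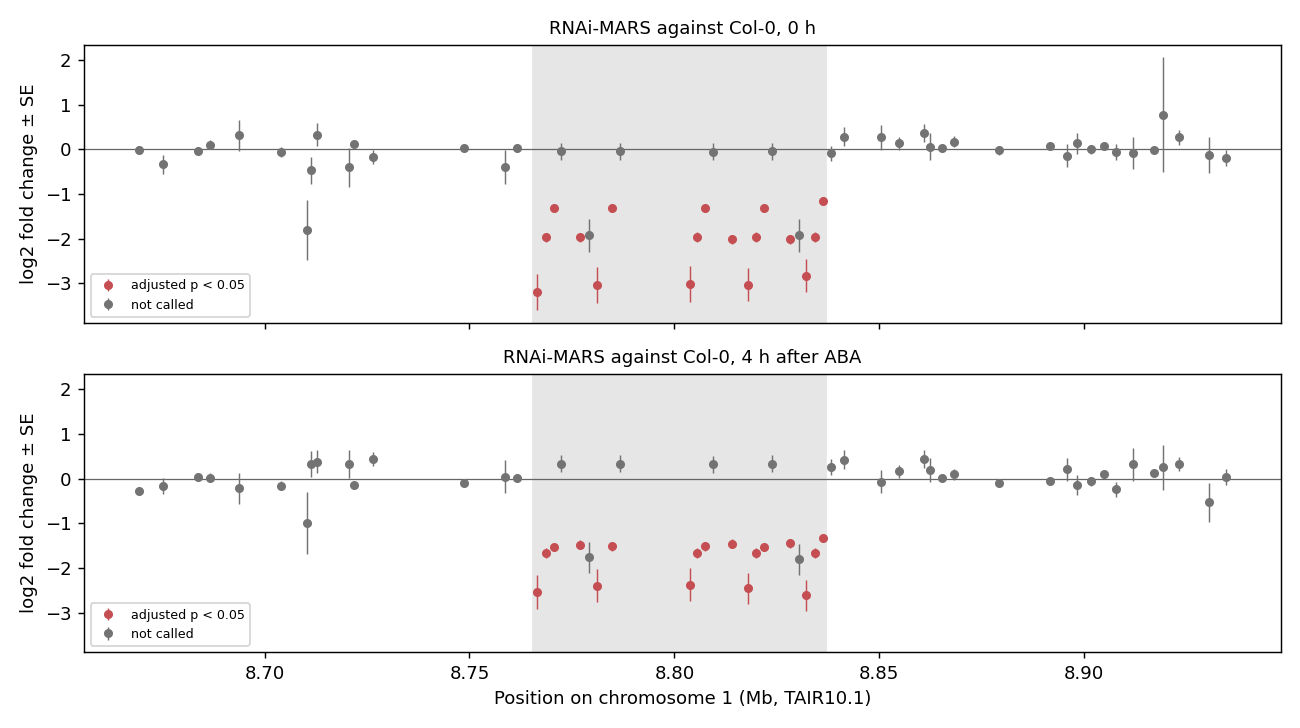
Log2 difference between RNAi-MARS and Col-0 (vertical axis, with SE bars) of tested genes by position on chromosome 1 in Mb (TAIR10.1), before ABA and after it in separate panels; red points have an adjusted p under 0.05 and the shaded span is the 71.4 kb segment. The 17 called genes lie inside the span below 0 in both panels, and none of 36 flanking genes is called.

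The remaining called genes lie elsewhere. AT4G34480, on chromosome 4 at 16480887 to 16484231, was lower in RNAi-MARS, with 35.8 ± 1.57 against 6.14 ± 0.928 CPM before ABA (-2.54 ± 0.16, adjusted p = 1.23e-05) and 52.9 ± 10.2 against 8.05 ± 1.35 after it (-2.71 ± 0.16). QQS (AT3G30720), a gene that affects starch content, was higher, with 3.31 ± 0.204 against 7.39 ± 0.560 CPM before (1.16 ± 0.14, adjusted p = 0.0045) and 3.68 ± 0.456 against 7.01 ± 0.700 after (0.93 ± 0.14, adjusted p = 0.0302). MAF5 (AT5G65080), a MADS-box relative of the flowering repressor FLC, is below the level of the naming rule and was chosen after its values were seen. It was 2.24 ± 0.30 higher before and 2.32 ± 0.28 higher after ABA (adjusted p = 0.0108 and 0.00478). Before ABA it was not called with limma-voom, the stricter filter, the compared groups alone or the segment summed. Nor was it called there without the 2 libraries of low root score, or without library B or C of either genotype. After ABA it was not called with the stricter filter or the compared groups alone, nor without library A of Col-0. Across the 20 genes the differences before and after ABA correlated at 0.971 (Spearman 0.765), but these genes were chosen by their calls and 17 are from the segment of copies with divided reads, so a high value was largely fixed and does not measure similarity. Without library C of Col-0 before ABA it was 0.557 over the genes then called, and across all genes, which are not independent replicates, it was 0.035. DESeq2 called 28 genes before ABA, which included these 20, and 77 after it, 13 of them shared. After ABA DESeq2 gave no adjusted p for QQS or MARS, so their absence from its calls there is not a test result. QQS after ABA was not called in 11 of 19 alternatives (highest adjusted p = 0.665), and without library C of Col-0 after ABA 55 genes were called there, 30 higher and 25 lower; that library had a heat shock list score of 2.23, against 0.0424 and 0.513 in the other libraries of its group.

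EdgeR called 0 members of the 26 tested lists between genotypes. There 973 features had an unadjusted p under 0.05 before ABA and 1981 after it, against 1123 that 22465 tests give by chance. Small p-values were thus in excess after ABA and not before it, though genes are not independent. DESeq2 called MARS, HSP70 and MBF1C before ABA and at least LHY after it. Without library C of Col-0 edgeR called MBF1C before ABA, and at least JAZ8 and WRKY40 after it. The members named after ABA come from the first further calls in order of identifier, so other list members may have been called. Before ABA the medians of several ABA lists lay below 0 in RNAi-MARS. The response markers had a median log2 difference of -0.51, with 26 of 31 negative, and the clade A phosphatases that hold back ABA signalling -0.45, with all 9 negative. The 12 cell cycle genes all lay above 0 (median 0.30), as with KNOLLE (0.33 ± 0.14) and CDKB2;1 (0.43 ± 0.14). With a preset correlation camera called 12 lists before ABA, 9 lower and 3 higher, among them the markers (adjusted p = 2.63e-08), the phosphatases (4.15e-05) and the cell cycle (5.02e-06), and none was kept with an estimated correlation (adjusted p = 0.559 to 0.734). The other lower lists were jasmonate (0.00257), circadian clock (0.00421), heat shock (0.00421), phosphate starvation (0.00421), ABA metabolism (0.00932), anthocyanin (0.0238) and other triterpenes (0.0238), and the other higher ones auxin response (0.00596) and stomatal lineage (0.0201). Only the markers, the phosphatases and the cell cycle kept the call on leaving out any library. Without library B of RNAi-MARS before ABA it was lost by other triterpenes (0.436), ABA metabolism (0.143), jasmonate (0.320), auxin response (0.143), anthocyanin (0.336) and stomatal lineage (0.336), and without its library A by clock (0.137) and heat shock (0.0544). Without its library C other triterpenes (0.139), anthocyanin (0.160), stomatal lineage (0.0663) and phosphate starvation (0.0663) lost it. Without library A of Col-0 before ABA other triterpenes (0.461), ABA metabolism (0.136), anthocyanin (0.328) and stomatal lineage (0.116) did, and without its library B other triterpenes (0.380), stomatal lineage (0.0658) and phosphate starvation (0.0717). Adjusted over the list alone, 2 clock and 2 heat shock genes were lower. After ABA only jasmonate genes, higher, and photosynthesis genes, lower, were called as lists (both adjusted p = 0.00718, and adjusted p = 0.910 with an estimated correlation), and adjusted over the list alone 2 clock genes were higher. Without library B of RNAi-MARS after ABA these became 0.157 and 0.909, without library A of Col-0 both became 0.103, and without library B of Col-0 jasmonate became 0.0539; fry called no list in either comparison.

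From 0 h to 4 h after the ABA spray 8979 of 22465 features changed in Col-0 (40.0%), with 4646 higher and 4333 lower. Of these, 1644 and 1002 changed by at least 2-fold. Without an unsprayed group at 4 h these changes cannot be credited to ABA alone. Among the named genes COR15A, a chloroplast protein of cold and drought acclimation, went from 8.49 to 921 mean CPM (6.78 ± 0.53, n = 3, adjusted p = 7.15e-06), and LTI78 (RD29A), a classic ABA marker, from 25.7 to 991 (5.27 ± 0.28). The acetyltransferase gene NATA1 (7.48 ± 1.05), the β-glucosidase gene BGLU24 (7.30 ± 0.47), the lipid transfer protein gene LTP4 (6.67 ± 0.67), the transcription factor gene NAC019 (5.79 ± 0.35) and the expansin gene EXPA16 (5.50 ± 0.30) rose as well. AT1G56300 (7.37) and COR15B (5.40) also rose but overlap neighbouring genes, and COR15A and COR15B divided reads in 41.7% of libraries. The clock gene LHY fell from 413 to 11.6 mean CPM (-5.15 ± 0.17, adjusted p = 1.91e-08), and so did the receptor kinase gene CRK30 (-3.66 ± 0.78), OXS3 (-3.53 ± 0.55) and, with overlapping neighbours, RVE1 (-3.46) and COL2 (-3.43). The phosphate starvation RNA IPS1 (-4.13 ± 1.49, adjusted p = 0.0496) lost its call in 5 of 6 fits that left out a library. AT5G35777 (-4.11) shares reads with a transposable element.

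In RNAi-MARS 9567 features changed (42.6%), 4849 higher and 4718 lower, with 1922 and 991 by at least 2-fold. COR15A rose from 6.29 to 1240 mean CPM (7.61 ± 0.55, adjusted p = 3.9e-06), LTP4 by 8.87 ± 0.78, BGLU24 by 7.80 ± 0.49, NATA1 by 7.33 ± 1.00, the ribonuclease gene RNS1 by 7.11 ± 0.77, LTP3 by 6.74 ± 0.85 and LTI65 (RD29B) by 6.37 ± 1.09 on the log2 scale. AT3G02480 rose by 8.93 ± 0.64, and LEA7, which overlaps another gene, by 7.62 ± 1.04. LHY fell again (-4.37 ± 0.17), with CRK30 (-3.05 ± 0.72), RVE8 (-2.53 ± 0.24), OXS3 (-2.40 ± 0.52), the light stress gene ELIP2 (-2.34 ± 0.40) and, with overlapping neighbours, COL2 (-3.16), BT5 (-2.78), BMY3 (-2.54), RVE1 (-2.39) and AO (-2.36).

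MARS itself rose from 0 h to 4 h after the spray in both genotypes. The rise was 2.44 ± 0.76 in Col-0 (adjusted p = 0.0265) and 3.82 ± 1.05 in RNAi-MARS (adjusted p = 0.0147). In Col-0 the call was lost without library B before ABA (0.0824), library A after it (0.0658) or library C after it (0.0583), with no filter on low counts (0.057) and with the compared groups alone (0.0903). In RNAi-MARS it was lost without library C before ABA (0.0559) and with limma-voom (0.111). The rise in Col-0 was 3.53 without library A before ABA and 3.38 with limma-voom. MRN1 was at 1.32 ± 1.05 in Col-0 and 1.46 ± 1.00 in RNAi-MARS (adjusted p = 0.346 and 0.270), CYP71A16 at -0.92 and -0.03, and CYP705A12 at 0.02 and 0.77, none of them called. Adjusted over the list alone MARS was the 1 called member of the cluster in each genotype. Within 100 kb of MARS, 15 of 34 tested genes changed in Col-0, 9 higher and 6 lower (16 adjusted over the list alone), and 14 changed in RNAi-MARS, 9 higher and 5 lower (14 adjusted over the list alone). They include the jasmonate synthesis gene AOS (1.32 ± 0.14 and 1.48 ± 0.14), AT5G42420 (1.24 and 1.34), AT5G42570 (1.03 and 0.90) and the exoribonuclease gene XRN2 (-0.70 and -0.85).

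ABA response markers rose as a group in both genotypes, 27 of 31 in Col-0 (28 adjusted over the list alone) and 30 of 31 in RNAi-MARS (31 adjusted over the list alone), and none fell. Examples are LTI30 (5.21 ± 0.29 and 4.92 ± 0.28) and NAC019 (5.79 and 6.15). Camera gave adjusted p = 8.29e-16 and 1.45e-18, and adjusted p = 0.260 and 0.179 with an estimated correlation. Of 9 clade A phosphatases, 7 rose in each genotype (7 adjusted over the list alone), such as ABI1 (1.98 ± 0.16 and 2.22 ± 0.16), ABI2 (2.06 and 2.38) and HAI3 (6.75 and 6.89); camera gave 0.00136 and 7.39e-05, and adjusted p = 0.692 and 0.411 with an estimated correlation. Among 8 tested kinases and transcription factors of the pathway 7 rose in Col-0 and 8 in RNAi-MARS (as many adjusted over the list alone), such as ABF1 (4.07 ± 0.10 and 4.18 ± 0.10), SNRK2.2 (1.55 and 1.58) and ABI5 (3.80 and 3.46). Their camera values were 0.000212 and 5.76e-06, and adjusted p = 0.217 and 0.101 with an estimated correlation. Fry, which does not compare a list with other genes, called the markers (7.48e-06 and 2.17e-06) and the phosphatases (0.00163 and 0.000303) in both genotypes. It also called the kinases and transcription factors (1.49e-07 and 3.61e-08). The receptors moved the other way, with 6 of 9 lower in each genotype (6 adjusted over the list alone), such as PYR1 (-1.04 ± 0.07 and -0.83 ± 0.07) and PYL4 (-1.93 and -1.94), while PYL7 rose in RNAi-MARS (0.38 ± 0.09). The receptor list passed camera in Col-0 (0.00742, and adjusted p = 0.293 with an estimated correlation; 0.156 without library A before ABA and 0.0749 without library B after it) and not in RNAi-MARS (0.0646), while fry called it in both (0.000122 and 0.000342).

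Genes of ABA turnover changed mostly upward. Of 11 metabolism genes 8 rose and 1 fell in each genotype (9 and 1 adjusted over the list alone in Col-0, 8 and 1 in RNAi-MARS), with the catabolic genes CYP707A1 (3.54 ± 0.31 and 3.85 ± 0.31) and CYP707A2 (2.94 and 3.68) and the glucosidase gene BGLU18 (2.77 and 2.86) among those that rose. Camera gave 0.00275 and 0.00428, and adjusted p = 0.326 and 0.411 with an estimated correlation. Jasmonate genes rose in 11 of 17 cases in Col-0 (12 adjusted over the list alone) and 16 of 17 in RNAi-MARS (16 adjusted over the list alone), with AOC2 (3.39 ± 0.32 and 4.17 ± 0.33), which divides reads with its relatives, and AOS among them. The camera values were 0.000212 and 1.41e-07, and adjusted p = 0.692 and 0.411 with an estimated correlation. Heat shock genes rose in 8 and 11 of 11 cases (8 and 11 adjusted over the list alone), such as HSP18.2 (1.49 ± 0.18 and 1.09 ± 0.18) and HSP17.4 (2.87 and 3.04), with camera at 0.00441 and 0.000202, and adjusted p = 0.692 and 0.411 with an estimated correlation. Library C of Col-0 after ABA had the highest heat shock score of all libraries (2.23). Aliphatic glucosinolate genes rose in 8 of 13 cases in each genotype (8 adjusted over the list alone), such as SOT17 (1.11 ± 0.14 and 1.05 ± 0.14), and 1 fell in Col-0. For them camera gave 0.00742 and 0.0112, and adjusted p = 0.692 and 0.698 with an estimated correlation. Fry called metabolism (0.000128 and 0.000147), jasmonate (0.00423 and 0.000303), heat shock (0.0152 and 0.0019) and glucosinolates (0.00423 and 0.00635) in both genotypes.

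Of 20 photosynthesis genes 6 fell and 1 rose in Col-0 (6 and 1 adjusted over the list alone) and 8 fell in RNAi-MARS (8 adjusted over the list alone). The small Rubisco subunit genes RBCS1B (-1.30 and -1.58) and RBCS2B (-1.23 and -1.61) divide reads in at least 91.7% of libraries and are uncertain singly. The list passed camera in RNAi-MARS (0.0018, and adjusted p = 0.766 with an estimated correlation) and not in Col-0 (0.0843), and fry gave 0.0323 and 0.306 in the same order. Clock genes changed in both directions, 9 higher and 7 lower of 22 in Col-0 and 11 higher and 7 lower in RNAi-MARS (the same counts adjusted over the list alone). The morning gene CCA1 fell (-2.48 ± 0.16 and -2.25 ± 0.16), while the later GI (2.54 ± 0.13 and 2.47 ± 0.13) and PRR5 (5.28 ± 0.39 and 5.74 ± 0.41) rose; camera gave 0.461 and 0.354, and fry 0.895 and 0.00881. The labels give hours after the spray and no time of harvest, so a difference in the time of day is not excluded. Among the genes named from these lists, ABI1, ABF1, PYL7, HSP17.4, KNOLLE and CDKB2;1 overlap neighbouring annotated genes and are uncertain to that extent.

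**Figure D3:**
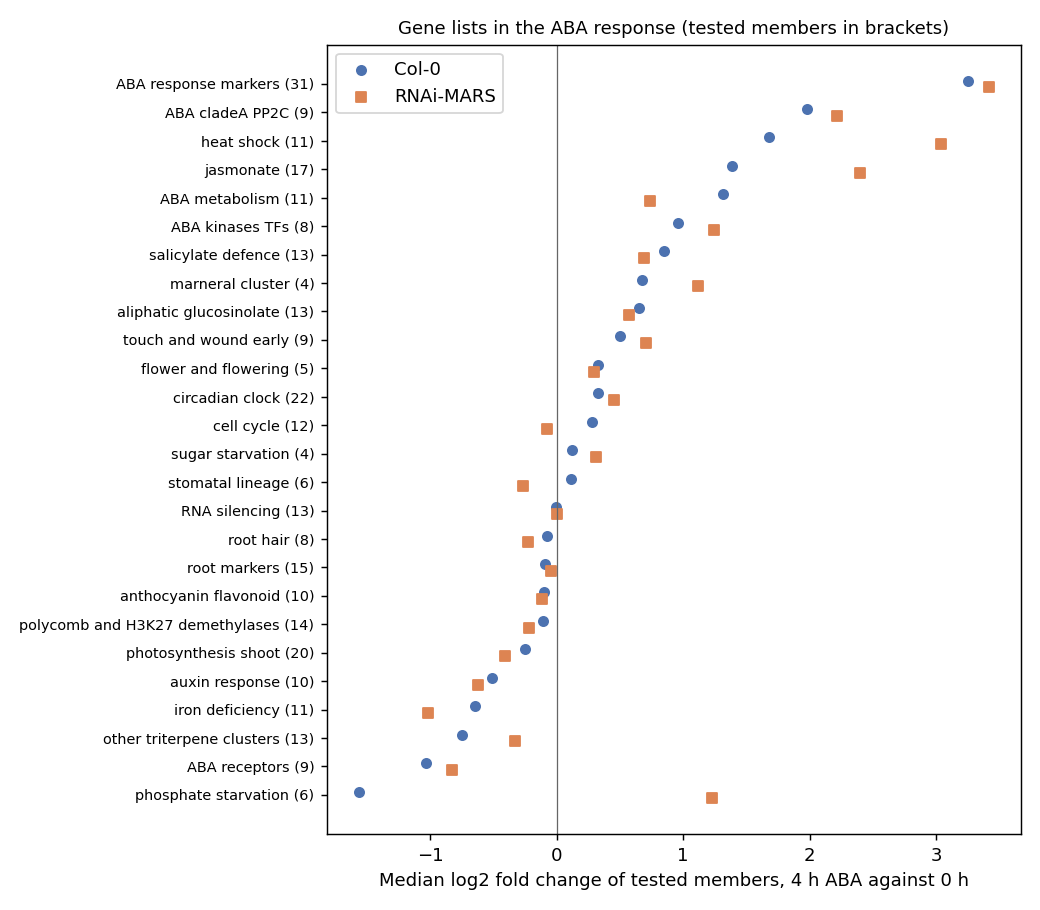
Median log2 fold change of each gene list at 4 h against 0 h in Col-0 and in RNAi-MARS, with the number of tested members in brackets after the list's name. The ABA response lists lie to the right of 0 and the ABA receptors to the left in both genotypes.

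Across genes, the changes from 0 h to 4 h were largely alike in size and direction in the 2 genotypes. They hold ABA, the spray and any difference in time of day together. Over the 11335 features called in either, the log2 fold changes correlated at 0.921 across genes (Spearman 0.929), with a slope of 1.07 and the same sign for 97.5% of them. Over all 22465 tested features the correlation was 0.867 (Spearman 0.840), with the same sign for 83.6%. The 11335 features were chosen by their calls in these same comparisons, which raises their likeness, and genes are not independent replicates. Of the called features 3755 rose in both, against 1003 for independent lists of these sizes, and 3454 fell in both, against 910. AT2G17630 and CYP82C2, chosen after their values were seen, were called in opposite directions. AT2G17630 was 0.43 ± 0.14 in Col-0 and -0.41 ± 0.14 in RNAi-MARS, with a difference of -0.85 ± 0.20 that did not pass (adjusted p = 0.946), and CYP82C2 had at most 1.05 mean CPM in any group.

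**Figure D4:**
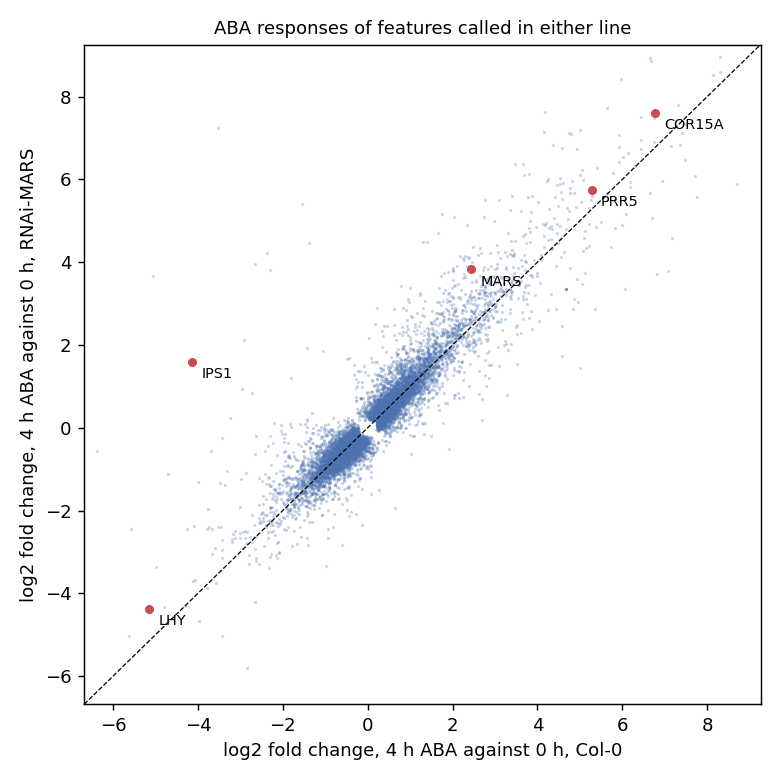
Log2 fold change from 0 h to 4 h in Col-0 (horizontal axis) and in RNAi-MARS (vertical axis), with a point for each of the 11335 features called in either and a dashed line of equality. The points follow the line (correlation 0.921), with COR15A and PRR5 high and LHY low in both genotypes.

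No gene differed in its ABA response between the genotypes by edgeR. The smallest adjusted p was 0.946, and 1076 features had an unadjusted p under 0.05, fewer than the 1123 that 22465 tests give by chance. Limma-voom called 0 and DESeq2 called 4, all with a more positive log2 change in RNAi-MARS: RVE1 (1.08 in DESeq2, adjusted p = 0.0264), ABCG27 (2.03, 0.00224), AT3G26510 (0.59, 0.0264) and AT5G17340 (11.1, 0.00742), chosen after their values were seen. RVE1 (-3.46 in Col-0 and -2.39 in RNAi-MARS) and AT3G26510 (-1.93 and -1.34) fell less in RNAi-MARS by these values, and ABCG27 rose more (1.22 and 3.24). MARS differed by 1.38 ± 1.33 (0.30 without library A of Col-0 before ABA and 0.07 with limma-voom), MRN1 by 0.14 ± 1.43, CYP71A16 by 0.88 ± 0.99 and CYP705A12 by 0.75 ± 1.21 (n = 3 per group, adjusted p of at least 0.947). As groups, 28 of 31 ABA response markers (median 0.62) and 16 of 17 jasmonate genes (median 0.78) had a more positive log2 change in RNAi-MARS, and all 12 cell cycle genes (median -0.36) and all 20 photosynthesis genes (median -0.21) a more negative one. Camera called 8 lists with the preset correlation, none with an estimated correlation (adjusted p of at least 0.588), and fry called none. No member was called over all genes. This comparison subtracts the genotype difference before ABA, from the same libraries. Lists called both there and here are therefore not separate findings. Adjusted over the list alone 2 clock genes, 1 receptor gene and 1 flowering gene were higher. On simulated counts of this comparison 84.8% of 4-fold but only 25.8% of 2-fold differences were recovered, so differences under 2-fold were mostly not detectable with these libraries.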

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

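The list tests and the splits in this part were planned, and no test here was chosen only after the result was seen. For 8 gene lists the log2 response to ABA differed between RNAi-MARS and Col-0 in a test of the difference itself, camera with a preset correlation. None of the 8 was called with an estimated correlation or by fry, and none of their members was called singly by edgeR. The test subtracts the genotype difference before ABA, so lists also called in that comparison are not separate findings. ABA response markers had a more positive log2 change in RNAi-MARS (adjusted p = 3.26e-06, median 0.62 on the log2 scale, 28 of 31 positive; adjusted p = 0.588 with an estimated correlation). Jasmonate genes did too (adjusted p = 3.26e-06, median 0.78, 16 of 17 positive). Cell cycle genes had a more negative change (adjusted p = 2.23e-05, median -0.36, 0 of 12 positive; medians of 0.28 in Col-0 and -0.08 in RNAi-MARS), with KNOLLE at -0.44 ± 0.20 and CDKB2;1 at -0.49 ± 0.20, which both overlap other genes. Phosphate starvation genes had a more positive change in RNAi-MARS (adjusted p = 0.000773, median 2.80, 6 of 6 positive), though the list passed in neither response alone (adjusted p = 0.187 in Col-0, median -1.57, and 0.674 in RNAi-MARS, median 1.23), with SPX1 at 2.13 ± 0.99. These 4 lists kept their call on leaving out any of the 12 libraries (highest adjusted p = 0.0025, 0.000664, 0.00402 and 0.0344 in the same order).

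The clade A phosphatases had a more positive change in RNAi-MARS (adjusted p = 0.0122, median 0.33, 9 of 9 positive), but 6 of the 12 fits that left out a library lost this: 0.391 without A of Col-0 before ABA, 0.0967 without C of Col-0 after it, 0.0692 and 0.0565 without B or C of RNAi-MARS before it, and 0.0829 and 0.0738 without B or C of RNAi-MARS after it. The ABA kinases and transcription factors gave adjusted p = 0.0224 (median 0.30, 7 of 8 positive), lost in 5 of 12 such fits: 0.0691 without A of Col-0 before ABA, 0.0967 without C of Col-0 after it, 0.108 without C of RNAi-MARS before it, and 0.0825 and 0.101 without B or C of RNAi-MARS after it. Clock genes gave adjusted p = 0.0119 (median 0.26, 15 of 22 positive), lost in 1 such fit, with 0.137 without library A of RNAi-MARS before ABA. Photosynthesis genes had a more negative change in RNAi-MARS (median -0.41, against -0.25 in Col-0; adjusted p = 0.00243, median difference -0.21, 0 of 20 positive), lost in 1 such fit, with 0.618 without library B of RNAi-MARS after ABA. With an estimated correlation the adjusted p was 0.780 for the phosphatases, 0.854 for photosynthesis and 0.588 for the remaining 6 lists.

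Libraries differed within groups in the same lists. The mean log2 level of the ABA response markers was -0.967, -1.35 and -2.19 in libraries A, B and C of Col-0 before ABA and -1.74, -2.40 and -2.36 in those of RNAi-MARS, while the libraries after ABA lay between 1.73 and 1.99. The mean of the phosphate starvation genes was 1.43, 1.93 and -0.0755 in Col-0 before ABA and -2.44, 0.126 and -0.423 after it, and 0.606, -0.645 and -1.28 in RNAi-MARS before ABA and 0.488, 2.04 and -1.75 after it.

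The count of genes whose ABA response differed between genotypes was 0, and 100 of 100 splits of the 12 libraries, the real one included, gave at least as many. With a real count of 0 this outcome was fixed in advance and says nothing about chance. Of these splits 98 called 0 genes, and the highest other count was 92. That split put together libraries A and B of Col-0 and A of RNAi-MARS before ABA. With them it put C of Col-0 and A and C of RNAi-MARS after ABA, against the rest. Picked as the highest, it cannot show whether some structure of the libraries crosses the genotypes, which was not tested. The split with the next highest count, 22, exchanged the genotypes at 4 h alone and so holds the genotype difference common to both times.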

How the results depend on the processing

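The alternatives that summed the chromosome 1 segment, used or filtered on the root score, left out transposable elements or added the block to the similarity were chosen only after the results were seen. Among counts of genes and similarities 206 of the alternative values kept their size and 32 moved. Among named genes 8363 kept direction and side of the threshold, 267 lost and 2 gained a call, and among list tests 1185 kept both, 99 lost and 41 gained a call and 1 turned direction. The size factors of DESeq2 moved the median log2 fold change by at most 0.00902 and the share of higher calls from 51.7% to 52.4% in Col-0 and from 50.7% to 51.9% in RNAi-MARS. Depth limits low genes such as MARS, which held 3 to 6 counts in RNAi-MARS before ABA.

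For the genotype effect after ABA, DESeq2 called 19 higher and 58 lower, and for the interaction 4 higher; the cause was not tested. Only 1 gene was higher before ABA with limma-voom, with the stricter filter, with the compared groups alone, with the segment summed and without the 2 libraries of low root score, and in each it was QQS. After ABA 1 gene was higher with the stricter filter, with glmTreat, with the segment summed, with the root score as a covariate and without the 2 libraries of low root score, and 0 with the compared groups alone, where fewer libraries were in the fit. The segment summed left 2 lower genes at each time, since 17 genes became 1. Tested against a 1.2-fold change, 3019 were higher and 2692 lower in Col-0 and 3329 higher and 2989 lower in RNAi-MARS, as small changes no longer counted. Over all tested genes the similarity was 0.867 for the ABA responses and 0.035 for the genotype effects, most of whose genes were not called.

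On leaving out a library, genes higher in RNAi-MARS ranged from 1 (without B or C of either genotype) to 2 before ABA and from 0 (without A of Col-0) to 30 (without C of Col-0) after it, with 1 without A or B and 4 without C of RNAi-MARS, and genes lower from 13 to 23 and from 13 to 25. The ABA response in Col-0 ranged from 3750 to 4277 higher and 3303 to 3723 lower, and that in RNAi-MARS from 3808 to 4552 higher and 3704 to 4443 lower; the interaction stayed at 0. Similarity ranged from 0.884 to 0.931 for the ABA responses and from 0.557 (without library C of Col-0 before ABA) to 0.978 for the genotype effects. The heat shock list in the genotype effect after ABA ranged from an adjusted p of 0.00652, in the opposite direction without library C of Col-0, to 0.8998, and the cause was not tested.

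The letters A to C were not treated as pairing the libraries, because a fixed rule asked every same-letter pair for a correlation of deviations over 0.1. Of 18 such pairs 8 passed (-0.299 to 0.403), with a median of 0.042 against -0.039 for pairs of different letters. Among the 12 libraries 7 correlated best with their own letter, so a partial pairing is not excluded. With the replicate block the calls were 2 higher and 21 lower before ABA and 1 higher and 15 lower after it, 4624 and 4393 in Col-0, 4876 and 4817 in RNAi-MARS and 0 for the interaction, and the similarities were 0.925 and 0.916.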

Other observations

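The tests of shared reads, of the segment, of root tissue and of the clock, and the correlations with the root score, were chosen only after the results were seen; the splits of the libraries were planned.

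Other lists moved in part after ABA, and none of those given here passed camera in either genotype. Salicylic acid and defence genes rose in 5 of 13 cases in each genotype (5 adjusted over the list alone, with 1 lower in RNAi-MARS), such as PAD4 (0.81 ± 0.20 in Col-0 and 0.69 ± 0.20 in RNAi-MARS). Auxin response genes fell in 5 of 10 cases in each genotype (5 adjusted over the list alone), with IAA1 at -1.38 ± 0.17 and -1.22 ± 0.17, and 2 rose in Col-0 (3 adjusted over the list alone). Iron deficiency genes fell, 3 of 11 in Col-0 (2 adjusted over the list alone) and 4 in RNAi-MARS (4), led by the iron transporter gene IRT1 (-5.62 ± 1.18 and -5.03 ± 1.00), which had 2.29 and 3.48 mean CPM at 0 h; fry called this list (adjusted p = 0.0313 and 0.0158). The anthocyanin regulator PAP1 rose (3.67 ± 0.54 and 4.17 ± 0.57), while the pathway's first enzyme CHS, which overlaps another gene, fell (-1.63 and -1.62); 2 of 10 genes of that list rose and 2 fell in each genotype (adjusted over the list alone 3 fell in Col-0 and 2 in RNAi-MARS). The stem cell regulator WOX5 rose (2.53 ± 0.55 and 1.85 ± 0.51) while SCR fell (-0.55 ± 0.09 and -0.54 ± 0.09), within a root marker list of 15 where 1 rose and 3 fell in Col-0 and 1 rose and 2 fell in RNAi-MARS (the same counts adjusted over the list alone).

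Some genes of chromatin and small RNA pathways fell slightly, in lists that did not pass camera, though fry called the polycomb list (adjusted p = 0.0313 and 0.0015). Of 14 polycomb genes 3 fell and 1 rose in Col-0 (2 and 1 adjusted over the list alone) and 5 fell and 1 rose in RNAi-MARS (5 and 1), such as BMI1B (-0.71 ± 0.15 and -0.55 ± 0.14). Of 13 RNA silencing genes 2 fell and 2 rose in Col-0 and 5 fell and 1 rose in RNAi-MARS (the same counts adjusted over the list alone), such as the methyltransferase gene HEN1 (-0.53 ± 0.10 and -0.54 ± 0.09) and AGO4 (-0.38 and -0.58). The flowering gene SOC1 rose (0.45 ± 0.16 and 1.17 ± 0.16), 1 of 5 in its list (0 and 1 adjusted over the list alone), and BCAT2, which overlaps another gene, rose in the sugar starvation list, 1 of 4 (2 and 1 adjusted over the list alone). Among 9 touch genes ZAT12 rose in Col-0 (1.36 ± 0.48; 0 adjusted over the list alone), and 3 rose and 2 fell in RNAi-MARS (3 and 2). In Col-0 4 of 12 cell cycle genes rose (3 adjusted over the list alone) and in RNAi-MARS 0 by edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05). Of 8 root hair and 6 stomatal genes edgeR called 0 (0 adjusted over the list alone), and at an unadjusted p under 0.05 there was 1, a stomatal gene in RNAi-MARS. Phosphate starvation had IPS1 lower in Col-0 (0 adjusted over the list alone), and the other triterpenes had THAA2 lower in RNAi-MARS (-1.66; 1 adjusted over the list alone). Of 574 tested transposable elements 54 rose and 74 fell in Col-0 and 70 rose and 70 fell in RNAi-MARS, and edgeR called 0 between genotypes, where 11 before and 74 after ABA had an unadjusted p under 0.05.

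Within groups, the cluster genes other than MARS followed the root score over 12 libraries, in a family of 5 relations tested by exact permutation within groups. CYP71A16 gave r = 0.882 (exact p = 0.00154, adjusted 0.00772; Spearman 0.951, exact p = 0.00231; r = 0.888 without the 2 libraries farthest from the median). CYP705A12 gave 0.762 (exact p = 0.0247, adjusted 0.0492; Spearman 0.755, exact p = 0.0285; 0.791 without them) and MRN1 0.692 (exact p = 0.0394, adjusted 0.0492; Spearman 0.727, exact p = 0.0394; 0.648). The mean of the other triterpene genes gave 0.731 (exact p = 0.0355, adjusted 0.0492; Spearman 0.776, exact p = 0.0255; 0.736), and MARS 0.602 (exact p = 0.192; Spearman 0.497, exact p = 0.189; 0.365).

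Of the 18 genes lower in RNAi-MARS 17 lie in a single chromosome 1 segment of near-identical copies. The segment summed, where division between the copies inside it cancels, stayed lower by a log2 difference of -1.86 ± 0.10 before ABA. That argues against reads divided between these copies as the whole cause. A difference of this stretch between the plant lines, in copy number, sequence or silencing, could give such a block and stays open. In the segment 19 tested genes lay below 0 at both times, but 4 genes similar to ASB1 had a median of -0.0422 before ABA; their sum follows ASB1 (CV of the ratio 13.1%, against 33.5% for ASB1), which borders the segment and was not called (-0.09 ± 0.18), so they may hold its reads and leave this open. An effect of MARS on the segment stays open too, as untested.

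Lower MARS in RNAi-MARS was set against a smaller share of root tissue. That share was not measured, and the root score of marker genes stood in for it. The other cluster genes follow the score, while for MARS itself this was not shown (r = 0.602, exact p = 0.192). If root share set both MARS and MRN1 they would fall together, but the log2 ratio of MARS to MRN1 differed between genotypes by -4.47 over both times (exact permutation p = 0.005, the smallest that the design allows, adjusted 0.015). Part of this ratio comes from MRN1, which was higher in RNAi-MARS by 1.62 (exact permutation p = 0.125), while MARS alone differed by -2.85. MRN1 may therefore carry a genotype difference of its own. As far as MRN1 tracks root share in both genotypes, the ratio argues against root share as the whole cause of the difference. Root share may still add to the spread of MARS within Col-0 before ABA (0.344 to 6.63 CPM). The knockdown itself remains a hypothesis from the same data, and reads of the construct, if any, would raise MARS in RNAi-MARS.

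Clock genes were changed between 0 h and 4 h in both genotypes, with 16 of 22 called in both and all 16 in the same direction. The time of day could give these changes without ABA, and ABA or the spray could also give them. These cannot be told apart, because no unsprayed group was collected at 4 h and the labels give no time of harvest.

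Of the 10 splits of the libraries before ABA 1, the real one, called as many as the genotypes' 20 genes, and the highest other split called 0. After ABA it was again 1 of 10, with 20 genes and 1 in the highest other. For the ABA response 1 of 10 splits called as many as the 8979 features in Col-0 and 1 of 10 as many as the 9567 in RNAi-MARS, with 0 in the highest other split of each. With 10 splits a share under 0.05 cannot be reached.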
